A study of Mus musculus with 3 samples.

How the data were processed

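Total RNA of NIH/3T3 mouse fibroblasts was measured on Illumina expression bead arrays, with 1 sample each for mock, 5aza-dC and recovery. Per the labels' protocols, RNA was extracted with TRIZOL and amplified and biotin-labelled with a TotalPrep kit, and per the series description each sample comes from duplicate independent experiments. The first deposited table holds, per the file headers, non-normalized signal intensity with a detection p-value for each of the 45281 probes, on a linear scale and without background subtraction. The second deposited table holds intensity after the authors' background subtraction and scaling, which is read from its values: 39.5%, 38.5% and 40.2% of the values of mock, 5aza-dC and recovery are below 0, and the mean is 224.5 in each. The software that made both tables is not given in the sources used here. The deposited tables correlated with r = 0.9997, 1.0000 and 1.0000 in mock, 5aza-dC and recovery. There were 0 columns of other samples.

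Signal ran from 48.3 to 30834.1 in mock, from 44.6 to 32233.3 in 5aza-dC and from 45.4 to 30614.3 in recovery, with means of 321.2, 277.3 and 255.1. At a detection p-value below 0.01, 14465, 15105 and 14070 probes were detected. Of the probes, 34885 were given 1 gene symbol, 18 matched several genes and were left out of the gene tables, and 10378 were not listed in the annotation used here and were examined only as probes. Entrez numbers matched 34807 probes, and 0 genes were renamed. Reference gene tables of the mouse assembly GRCm38.p6 served only for gene names and the order of neighbouring genes. A gene was represented by 1 probe, that with the highest mean over the 3 groups, and 8155, 8692 and 8070 genes were detected in mock, 5aza-dC and recovery.

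The main values were made with the neqc function of limma 3.58.1 in R 4.3.3 (normexp background correction from the detection p-values, offset 16, quantile normalization, log2). A gene was called at an absolute log2 difference of at least 1.0 with detection in the brighter group. The design assumed 1 array per group and no test, as the labels give 1 column per group. The detection p-values of the deposited columns move in steps that fit 2 arrays with 936 negative controls each (100.0% lie on steps of 0.5 control). The 2 arrays behind each column were therefore solved from both tables, using p-values between 0.05 and 0.97, and this step and every limma test on it were added after the data had been examined. The misfit of the recomputed detection p-values had an SD of 9.81e-04, 8.82e-04 and 9.48e-04 in mock, 5aza-dC and recovery, against 3.23e-02, 3.21e-02 and 3.03e-02 with 1 array. Arrays of a pair correlated with r = 0.9953, 0.9978 and 0.9973, against 0.9492 to 0.9538 between mock and 5aza-dC. Between mock and recovery r was 0.9769 to 0.9818, and between 5aza-dC and recovery 0.967 to 0.9681. The 6 recovered arrays were normalized in the same way and fitted with limma (lmFit, eBayes, 3 residual and 3.79 prior degrees of freedom, 8982 genes), with Benjamini-Hochberg adjustment at 0.05 within each of 3 comparisons. A lower bound of the fold was given where neither array of the dimmer group detected the gene.

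The gene list values are the median log2 differences of the detected members, placed among 10000 random lists matched on expression in 20 bins, with limits at 2.5% and 97.5%. The 27 lists, fixed before the data were examined, cover germ cell genes of transposon control, meiosis, spermatids, oocytes, X-linked germ cell genes, imprinted genes, pluripotency, interferon-stimulated genes, class I antigen presentation, p53 targets, mitosis, DNA replication, DNA methylation machinery, deoxycytidine analog handling, fibroblast matrix, contractile genes, skeletal muscle, adipocytes, epithelium, blood cells, endothelium, neural genes, cholesterol synthesis, stress response, oxidative stress and metals, NF-kB responsive cytokines and loading controls. Lists of growth factor responsive genes and of ribosome assembly factors were written after the named genes had been seen. The rule for naming genes, also fixed before the data were examined, takes the 12 largest called differences each way against mock and 6 each way between recovery and 5aza-dC. It adds all detected germ cell genes of transposon control, the DNA methyltransferases and Uhrf1, and up to 4 called members of each other list, or the 1 detected member with the largest difference where no member was called. Genes named outside this rule are said to have been chosen after their values were seen.

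The scripts were tested on simulated data. Recovery of 2 averaged arrays from a simulated mock column of 45281 probes returned a scale ratio of 1.3019 against a true 1.3017. The median error was 0.058%, taken only over probes well above background. Weaker signals were not checked in this way. Nor were pairs with closer scale factors, as in 5aza-dC (1.1369 and 0.9397) and recovery (1.2465 and 1.0622). For 5aza-dC minus mock over 8982 genes, limma found 44 of 50 genes changed 1.5-fold (88%) and all 50 at 2-fold, 4-fold and 8-fold, with 15 false calls, and 2 calls in a comparison without changes. The list step found 39 of 40 lists of 25 genes shifted by 0.5, and 3 of 40 unshifted lists lay outside the limits. Where 2 or more probes of a gene were detected (3355 genes), the brightest and second brightest correlated with r = 0.82 for 5aza-dC minus mock and 0.63 for recovery minus mock. Of 190 genes called higher on the brightest probe, 98.4% were above 0 on the second and 49.5% were 2-fold higher there.

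Alternatives covered the offset (50), no background correction, other scalings, the second deposited table, detection filters, the choice of probe, thresholds of 1.5-fold and 3-fold, and each recovered array left out in turn. Tables and figures were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, scikit-learn 1.9.0, statsmodels 0.14.6 and matplotlib 3.10.9. DNA methylation itself was not measured in the data used here.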

Results

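NIH/3T3 cells, a mouse fibroblast line, were profiled on Illumina bead arrays in 3 groups. The mock group was mock treated. The 5aza-dC group was exposed for 3 days to 1 uM 5aza-dC (decitabine), a cytidine analog that is built into DNA and blocks DNA methyltransferases. The recovery group was exposed in the same way and then grown for 14 days without the drug. The deposited tables give 1 column of probe intensity per group, each the mean of 2 arrays, over 45281 probes. The median signal was 63.8 in mock, 61.2 in 5aza-dC and 61.1 in recovery, and 31.9%, 33.4% and 31.1% of the probes were detected. In all, 19057 named genes were measured and 8982 were detected in at least 1 group. The levels on the 2 arrays behind each column were computed back from the deposited tables, an analysis chosen after the data had been seen, and were tested with limma. The values of single genes are limma log2 differences ± SE with n = 2 arrays per group, and a gene is said to have risen or fallen only where it passed limma with Benjamini-Hochberg adjustment at 0.05. The number of arrays limits the precision, and the p-values measure only the spread between these arrays. The sources do not say whether the 2 arrays of a group are the duplicate independent experiments or repeat measurements of 1 RNA, and in the latter case the SE and p-values hold no variation between cultures. A gene was called when the deposited columns differed at least 2-fold and it was detected in the brighter group. Where neither array of the dimmer group detected the gene, the difference of a risen or fallen gene is given as a bound (at least N-fold).

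The comparison of 5aza-dC with mock asks which genes change expression when DNA methylation is inhibited. Interferon-stimulated genes, class I antigen presentation genes, keratins, germ cell genes and some imprinted genes were higher in 5aza-dC. Contractile genes and many matrix genes were lower. The Rsad2 transcript, which codes for an antiviral enzyme, rose most, by 6.60 ± 0.11, and Sema7a, a membrane-bound semaphorin, had the largest fall (-3.50 ± 0.09). Of the 8982 detected genes, 588 were called higher and 249 lower, so 70.3% of the called genes were higher. At least 4-fold differences were seen for 135 genes that were higher and 12 that were lower. All 837 called genes passed limma, and in all 837 the levels of the 2 arrays of one group lay outside those of the other, which picking genes by a 2-fold difference of the same arrays largely fixes. By limma alone, without a minimum fold, 2708 genes rose and 2434 fell (30.1% and 27.1%). Scaling to the median of all probes, which lies at background level, put the median difference of all genes at -0.15 here, at -0.28 for recovery minus mock and at -0.16 for recovery minus 5aza-dC, against 0.01, 0.03 and 0.02. With that scaling 521 genes were called higher and 420 lower in 5aza-dC (55.4% higher), and 570 rose and 397 fell by limma. An offset of 50 gave 313 called higher and 133 lower, and no background correction gave 282 and 118.

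**Figure D1:**
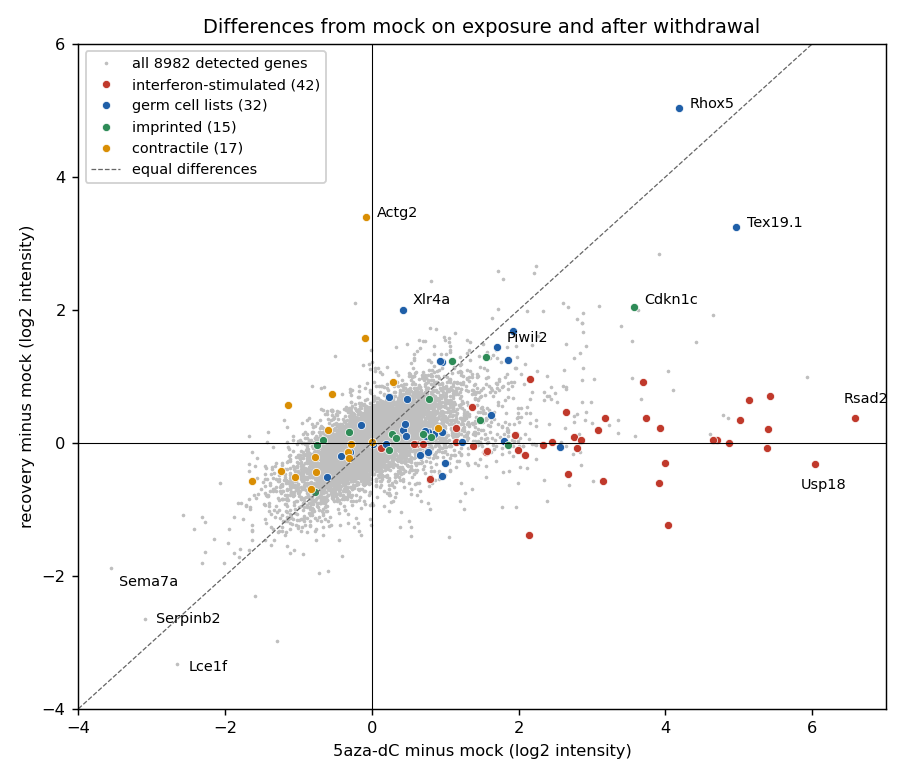
Log2 difference 5aza-dC minus mock (horizontal axis) against log2 difference recovery minus mock (vertical axis) for the 8982 detected genes, 1 grey point per gene, from the deposited columns. Red points are 42 interferon-stimulated genes, blue points 32 germ cell genes, green points 15 imprinted genes and orange points 17 contractile genes, and the dashed line marks equal differences; the interferon-stimulated genes lie far to the right (median 2.78) and near 0 on the vertical axis (median 0.01).

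Antiviral and interferon-induced genes made up most of the largest rises. Rsad2 was followed by Usp18 (6.10 ± 0.15), which removes the ubiquitin-like protein ISG15 from its targets. Ifit3, an antiviral RNA-response protein, rose by 5.40 ± 0.08. The interferon-inducible GTPases rose as well, with Igtp at 5.34 ± 0.12, Irgm2 at least 41.9-fold higher and Mx2 at least 33.6-fold higher. Further large rises were those of Parp14 (5.17 ± 0.18), the chemokine Cxcl10 (4.96 ± 0.19), Apol9a (4.83 ± 0.07), Apol9b (4.75 ± 0.11) and the mitochondrial nucleotide kinase Cmpk2 (at least 27.3-fold). Of the 49 measured genes of the interferon-stimulated list, 42 were detected, 41 rose, none fell and Zbp1 (0.13 ± 0.08), named after its values had been seen, did not pass; adjusted over the list alone, 41 rose. The median of this list was 2.78, or 2.54 with undetected genes at their bound, against -0.17 to 0.21 for the central range of 10000 random lists matched on expression. All 17 detected genes of the class I antigen presentation list (23 measured) rose, and 17 did so adjusted over the list alone, with a median of 1.78 against a random range of -0.26 to 0.34. Its largest rises were those of H2-Q8 (at least 6.10-fold), H2-T10 (2.86 ± 0.11), Nlrc5 (2.80 ± 0.07), the transactivator of class I genes, and H2-D1 (2.77 ± 0.08). In the NF-kB responsive cytokine and chemokine list, 12 of 16 detected genes (25 measured) rose and 1 fell, both over all genes and adjusted over the list alone. Its median was 0.73 against a random range of -0.30 to 0.31, and its examples were Ccl7 (2.30 ± 0.10), Ccl2 (1.79 ± 0.10) and Ccl8 (at least 2.65-fold). Cd74 (1.99 ± 0.13), also on that list, is itself neither a cytokine nor a chemokine. The adjusted p-values of the genes named here as risen ran from 1.55e-07 for Mx2 to 4.16e-05 for Cd74 (limma with Benjamini-Hochberg adjustment). Class I genes, Apol9a and Apol9b and several other interferon-induced genes have close paralogs, and bead probes may not separate them.

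Germ cell genes of transposon control, the subject of the series title, were also higher. The transcript of Tex19.1, a germ cell protein that restrains retrotransposons, was at least 24.98-fold higher in 5aza-dC. Transcripts of the PIWI proteins, which bind piRNAs, rose with it, Piwil2 at least 2.81-fold and Piwil4 at least 2.49-fold, and so did that of the RNA-binding protein Dazl at least 2.72-fold. Smaller rises were those of Tdrd7 (1.64 ± 0.09), Ddx25 (0.74 ± 0.10), Asz1 (at least 1.69-fold), Mov10l1 (at least 1.35-fold), Tdrd12 (at least 1.23-fold) and the germ cell helicase Ddx4 (at least 1.20-fold). Values for the remaining detected members were -0.12 ± 0.08 for Tdrkh and -7.20e-04 ± 0.08 for Dnd1. Of 31 measured genes of this list 12 were detected, 10 rose and none fell, also adjusted over the list alone, and the adjusted p-values by limma with Benjamini-Hochberg adjustment ran from 1.55e-07 for Tex19.1 to 0.0364 for Dazl. The median was 0.94, or 0.80 with undetected genes at their bound, against a random range of -0.30 to 0.43. Over genes detected in all 3 groups it was 0.39 and without a detection filter 0.06, both within their random ranges. Among X-linked germ cell and reproductive homeobox genes (36 measured, 7 detected), 6 rose and none fell, while adjusted over the list alone 6 rose and 1 fell. Rhox5, a reproductive homeobox gene, rose by 4.19 ± 0.09, Tex13b was at least 2.49-fold and Rhox9 at least 1.60-fold higher. The median of the X-linked list was 0.96 (0.72 at the bounds) against a random range of -0.35 to 0.64, and 0.04, within its range, without a detection filter. In the meiosis list (28 measured, 8 detected) 6 genes rose and 1 fell, also adjusted over the list alone, and the germ cell transcription factor Taf7l was at least 4.33-fold higher. The median of the meiosis list, 0.66, lay above its random range of -0.35 to 0.55, but it was 0.44 with undetected genes at their bound, and 0.34, within its range, over genes detected in all 3 groups. Few spermatid and oocyte genes were detected. Both detected spermatid genes of 33 measured rose, Tssk6 at least 1.18-fold, and of 3 detected oocyte genes (19 measured) 2 rose and 1 fell, with Gdf9 at least 1.37-fold higher, and the counts were the same adjusted over the list alone. The medians of the spermatid list (0.35) and the oocyte list (0.65) lay within their random ranges of -0.66 to 1.23 and -0.43 to 0.90.

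Genes listed as imprinted (expressed from 1 parental copy in some tissues) moved both ways, and their imprinting in these cells was not measured. Of 40 measured, 15 were detected, 11 rose and 4 fell, also adjusted over the list alone, with a median of 0.69 against a random range of -0.28 to 0.36. With undetected genes at their bound that median was 0.32, for which no random lists were drawn. With the series matrix values it was 0.30 and without a detection filter 0.01, each within its range. The growth inhibitor Cdkn1c rose by 3.54 ± 0.09, Phlda2 by 1.80 ± 0.12 and the signalling adaptor Gab1 by 1.59 ± 0.09, and the growth factor Igf2 was at least 2.14-fold higher. In the pluripotency list (26 measured, 8 detected) 3 genes rose and 3 fell, also adjusted over the list alone, and its median of 0.09 lay within the random range of -0.40 to 0.50. Dppa4 was at least 3.88-fold higher, Dppa5a rose by 1.33 ± 0.08 and the transcription factor Tbx3 fell by 1.22 ± 0.07.

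Genes of other cell types moved as follows. Of 12 detected epithelial genes (27 measured), 10 rose and 1 fell, also adjusted over the list alone, with a median of 1.58 (1.36 at the bounds) against a random range of -0.30 to 0.47. That epithelial median was 0.91 with an offset of 50, 0.83 without background correction, 0.95 with a detection p-value below 0.05 and 0.13 without a detection filter, each still above its range. The keratins Krt14 and Krt8 rose by 4.37 ± 0.11 and 4.03 ± 0.10, and the tight junction genes Cldn6 and Cldn4 were at least 5.86-fold and 2.81-fold higher. Neural genes (27 measured, 9 detected) rose in 7 cases and fell in 1, also adjusted over the list alone, with Uchl1, a neuronal deubiquitinase, at 1.84 ± 0.13. The neural median of 0.60 exceeded its random range of -0.27 to 0.57, but it was 0.25 with undetected genes at their bound and -0.15 over genes detected in all 3 groups. Blood and immune cell genes gave 2 rises and no fall among 4 detected (25 measured), or 3 rises adjusted over the list alone, and the lysosomal membrane protein Laptm5 was at least 3.27-fold higher. Endothelial genes (18 measured, 7 detected) rose in 5 cases and fell in 1, also adjusted over the list alone, and the VEGF receptor Flt1 fell by 0.97 ± 0.10. Adipocyte genes (19 measured, 8 detected) rose in 4 cases and fell in 2, also adjusted over the list alone, with the adipocyte regulator Pparg at 1.42 ± 0.10, the lipase Pnpla2 at 1.07 ± 0.08 and Dgat2 at -1.24 ± 0.07. Skeletal muscle genes (25 measured, 9 detected) rose in 4 cases and fell in none, also adjusted over the list alone, with the troponin Tnnt1 at least 2.85-fold higher. The medians of the blood (0.61), endothelial (0.42), adipocyte (0.45) and skeletal muscle (0.05) lists lay within their random ranges.

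Among the largest falls were those of the growth factor Hbegf (-2.32 ± 0.07), the early transcription factor Egr3 (-2.50 ± 0.13), the ERK phosphatase Dusp5 (-2.16 ± 0.07) and the kinase-like protein Trib1 (-2.29 ± 0.09). Serpinb2, a plasminogen activator inhibitor, fell by 3.05 ± 0.13, Lce1f by 2.56 ± 0.14, the death receptor Tnfrsf21 by 2.44 ± 0.09, Pus7l by 2.25 ± 0.12 and Hivep3 by 2.01 ± 0.11. The pseudogene-named transcript Hmga2-ps1 fell by 2.31 ± 0.11, and Ivl was at least 2.97-fold lower. In the contractile and SRF-responsive list (20 measured, 17 detected) 11 genes fell and 2 rose, also adjusted over the list alone, with a median of -0.54 against a random range of -0.25 to 0.23. Its largest falls were those of the matricellular genes Ccn1 (-1.64 ± 0.07) and Ccn2 (-1.05 ± 0.08), the transcription factor Srf (-1.23 ± 0.08) and the actin-binding protein Tagln (-1.14 ± 0.08). Fibroblast matrix genes (40 measured, 28 detected) fell in 15 cases and rose in 8, also adjusted over the list alone, with a median of -0.29 against a random range of -0.18 to 0.18. Over 11 alternatives that matrix median ran from -0.44 to -0.09, outside its range in each. Tenascin (Tnc) fell by 1.44 ± 0.07 and Thbs1 by 1.03 ± 0.08, while decorin (Dcn), also on the imprinted list, rose by 1.10 ± 0.11. Cholesterol synthesis genes (18 measured, 17 detected) fell in 10 cases and rose in none, or fell in 12 adjusted over the list alone, with a median of -0.36 against a random range of -0.28 to 0.25. The kinase Mvk of the mevalonate pathway differed by -0.62 ± 0.09. The adjusted p-values of the falls, with that of Sema7a, ran from 9.00e-07 for Sema7a to 0.00144 for Mvk (limma with Benjamini-Hochberg adjustment).

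Cell division genes were slightly higher in 5aza-dC. In the mitosis list (38 measured, 26 detected) 18 genes rose and none fell, or 20 rose adjusted over the list alone, with a median of 0.41 against a random range of -0.19 to 0.20 and the kinesin Kif2c at 0.87 ± 0.10. DNA replication genes (39 measured, 33 detected) rose in 13 cases and fell in 2, also adjusted over the list alone, with Gins2 at 0.81 ± 0.10; their median of 0.19 lay just above the random range of -0.20 to 0.16 and was 0.15, within its range, with the series matrix values and -0.04 with scaling to the median of all probes. Of 31 detected genes switched on by p53 (35 measured), 15 rose and 9 fell, also adjusted over the list alone, with a median of 0.19 inside the random range of -0.23 to 0.23, though at 0.17 above its range with an offset of 50 and without background correction. The examples were Tap1 (1.99 ± 0.16), which is also a class I antigen presentation gene, Trp53inp1 (1.57 ± 0.08) and the DNA damage sensor Ddb2 (1.39 ± 0.12). The drug's own pathway showed opposite changes: cytidine deaminase (Cda), which inactivates deoxycytidine analogs, rose by 1.73 ± 0.14, and the nucleoside transporter Slc29a2 was at least 2.43-fold lower. All 11 genes of that list were detected, 3 rose and 5 fell, also adjusted over the list alone, and the median was -0.10 against a random range of -0.32 to 0.29. Of the DNA methylation machinery (25 measured, 18 detected), 8 genes rose and 4 fell, also adjusted over the list alone, with a median of 0.23 inside the random range of -0.28 to 0.26, though outside its range at 0.13 to 0.40 under 5 alternatives. The de novo methyltransferase Dnmt3b fell by 1.62 ± 0.11, Gadd45a rose by 1.59 ± 0.12, the histone chaperone Daxx by 1.26 ± 0.10 and the hemimethylated DNA reader Uhrf1 by 0.39 ± 0.13. The maintenance methyltransferase Dnmt1 differed by -0.28 ± 0.13 and did not pass (adjusted p = 0.110, limma with Benjamini-Hochberg adjustment), and Dnmt3a and Dnmt3l were not among the detected genes. Stress response genes (27 measured, 23 detected) rose in 10 cases and fell in 6, with Ddit3 at 1.75 ± 0.20, Atf3 at 1.07 ± 0.13 and Ppp1r15a at 1.00 ± 0.11. Oxidative stress and metal response genes (19 measured, 15 detected) rose in 6 cases and fell in 2, with Cbr3 at 1.75 ± 0.08, Nqo1 at 1.23 ± 0.08, Gsta1 at least 2.01-fold and Aldh3a1 at least 1.64-fold higher. Of 14 detected loading control genes (15 measured), 1 rose and 4 fell, and the gene that rose was B2m (0.99 ± 0.07), which is also a class I antigen presentation gene. The counts of these last 3 lists were the same adjusted over the list alone, and their medians of 0.10, 0.24 and -0.10 lay within their random ranges.

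**Figure D2:**
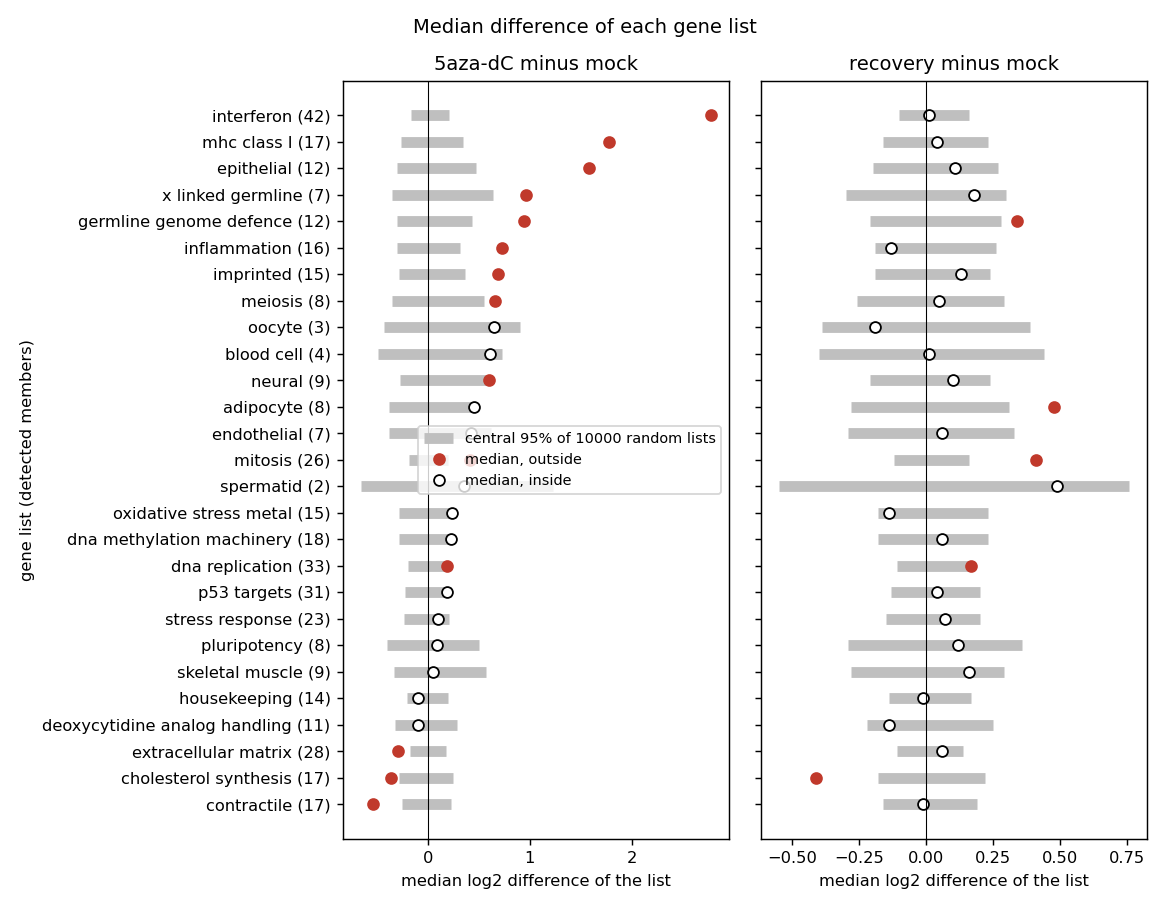
Median log2 difference of the detected genes of each of the 27 gene lists, for 5aza-dC minus mock (left) and recovery minus mock (right), each panel with its own horizontal axis. Grey bars span the central 95% of 10000 random lists matched on size and expression; red points lie outside the bar and open points inside, with interferon-stimulated genes at 2.78 on the left and 0.01 on the right.

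The comparison of recovery with mock asks what is left, or newly changed, 14 days after the drug was withdrawn. The same mock sample served both comparisons with mock, and its labels give no time in culture. In any comparison with recovery, effects of the added 14 days in culture therefore cannot be told apart from those of the drug and its withdrawal. The interferon-stimulated genes were back near mock, whereas Rhox5, Tex19.1 and some other germ cell and imprinted genes were still higher. Rhox5 had the largest rise (5.06 ± 0.09), followed by the smooth muscle actin Actg2 (3.38 ± 0.07) and by Tex19.1, which was at least 7.63-fold higher. The next were the transporter Slc47a1 (at least 5.21-fold), the proteoglycan Sdc3 (2.65 ± 0.07), the caveolar protein Cavin2 (2.57 ± 0.08), the complement protease Masp1 (2.58 ± 0.08) and the matrix proteoglycan Prelp (at least 4.77-fold). Epb41l4a (2.43 ± 0.10), Crip2 (2.13 ± 0.09), Srpx2 (2.08 ± 0.09) and the growth factor Bmp4 (2.06 ± 0.08) were the last of the 12 largest rises in the deposited columns. The largest falls in the deposited columns were those of Lce1f (-3.20 ± 0.14), the lipase inhibitor Angptl4 (-2.99 ± 0.07), Serpinb2 (-2.63 ± 0.13), the natriuretic peptide Nppb (-2.29 ± 0.07) and the transcriptional repressor Bhlhe40 (-1.84 ± 0.18). The growth factor Pdgfb (-1.95 ± 0.09), Sema7a (-1.88 ± 0.09), Hbegf (-1.81 ± 0.07), the ribosome assembly factor Ppan (-1.61 ± 0.16), the polymerase subunit Polr2g (-1.44 ± 0.29), Ivl (at least 2.60-fold lower) and Tnik (at least 2.48-fold lower) completed the 12 largest falls in these columns. Adjusted p-values of these genes ran from 2.01e-06 for Rhox5 to 0.00874 for Polr2g (limma with Benjamini-Hochberg adjustment). In all, 152 genes were called higher and 139 lower (52.2% higher), with 16 and 4 differing at least 4-fold, and 152 and 138 of them passed limma. The exception was Idh2 (-0.86 ± 0.36), named here after its values had been seen. By limma alone, 1994 genes rose and 1662 fell. With scaling to the median of all probes the split was 73 higher and 467 lower (13.5% higher), and 67 rose and 283 fell by limma.

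The lists fell into those that were back near mock and those that were not. In the interferon-stimulated list 7 genes rose, 6 fell and 29 did not pass, also adjusted over the list alone, with a median of 0.01. That median was -0.05, outside its range, with scaling to the median of all probes, which put the median of all genes at -0.28. It lay above its range with cyclic loess (0.16) and with scaling to probes detected on all 3 arrays (0.29). Ccl5 (-1.36 ± 0.09) and Oas1g (-1.23 ± 0.07) fell below mock. In the class I list 4 genes rose and 2 fell, or 3 and 2 adjusted over the list alone, around a median of 0.04, with Nlrc5 at 1.35 ± 0.07 and H2-D1 at 1.26 ± 0.08. Epithelial genes rose in 3 cases and fell in 2, also adjusted over the list alone, and Krt14 (1.45 ± 0.11) and Krt8 (1.10 ± 0.10) had rises smaller than in 5aza-dC, while the desmosomal Pkp1 fell by 1.23 ± 0.08. In the germ cell list of transposon control, 6 genes rose and none fell, also adjusted over the list alone, with a median of 0.34 (0.34 at the bounds) against a random range of -0.21 to 0.28. That median was 0.11 with a detection p-value below 0.05, 0.13 over genes detected in all 3 groups and 0.04 without a detection filter, each within its random range. Piwil2 was at least 2.34-fold, Asz1 at least 2.06-fold and Mov10l1 at least 1.64-fold higher than mock, and Tdrd7 (0.45 ± 0.09) and Tdrkh (0.29 ± 0.08) rose slightly. Piwil4 (0.04 ± 0.08), Tdrd12 (0.11 ± 0.14), Ddx25 (-0.13 ± 0.10), Ddx4 (0.19 ± 0.13) and Dnd1 (-0.02 ± 0.08) did not pass. Dazl did not pass either (0.78 ± 0.59, adjusted p = 0.323, limma with Benjamini-Hochberg adjustment), with levels of 4.19 and 6.29 on the 2 recovery arrays. Of the X-linked genes, Xlr4a was at least 2.58-fold and Tex13b at least 2.12-fold higher, and among imprinted genes Cdkn1c (2.02 ± 0.09), Gab1 (1.32 ± 0.09) and Dcn (1.23 ± 0.11) rose. The medians of these 2 lists, 0.18 and 0.13, lay within their random ranges of -0.30 to 0.30 and -0.19 to 0.24. The X-linked median was above its range without background correction (0.21), with scaling to the median of all probes (0.19) or of probes detected on all 3 arrays (0.53), and over genes detected in all 3 groups (2.27). The last value rests on few genes. It leaves out Tex13b, Rhox9 and Xlr4a, which were not detected in mock, and keeps Rhox5, at 5.04 in the deposited columns.

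Mitotic genes were above mock in recovery with a median of 0.41 against a random range of -0.12 to 0.16, with 18 that rose and none that fell, or 19 and 2 adjusted over the list alone, and Kif11 at 1.01 ± 0.08. Scaling to the median of all probes, which put the median of all genes at -0.28, gave a mitosis median of 0.02, still outside its range. Under that scaling it was 0.16 for 5aza-dC minus mock, also outside its range, and -0.21 for recovery minus 5aza-dC. DNA replication genes rose in 12 cases and fell in 3, also adjusted over the list alone, among them a fall of Rfc4 (-0.86 ± 0.19), and their median of 0.17 (random range -0.11 to 0.16) was 0.15, within its range, on the recovered arrays and turned to -0.22 with scaling to the median of all probes. Cholesterol synthesis genes fell in 11 cases and rose in none, also adjusted over the list alone, with a median of -0.41 against a random range of -0.18 to 0.22 and Fdps at -0.89 ± 0.07. Adipocyte genes rose in 5 cases and fell in 3, also adjusted over the list alone, with a median of 0.48 (0.35 at the bounds) against a random range of -0.28 to 0.31. That median was 0.19 with the series matrix values and 0.33 over genes detected in all 3 groups, both within their ranges, and -0.04 without a detection filter; Plin4 (1.17 ± 0.13) and Pparg (1.03 ± 0.10) rose and Cebpd fell by 0.92 ± 0.25. Contractile genes rose in 5 cases and fell in 5, or rose in 6 adjusted over the list alone, with a median of -0.01, and the myosin light chain Myl9 rose by 1.55 ± 0.08. That contractile median was -0.18, outside its range, with the mean of all detected probes. With scaling to the median of all probes it was -0.39, within its range under that scaling. Matrix genes rose in 12 cases and fell in 6, also adjusted over the list alone, and the protease Mmp2 rose by 1.07 ± 0.08. Their median of 0.06 was -0.16, outside its range, with scaling to the median of all probes, which put the median of all genes at -0.28. It was 0.18, above its range, with scaling to probes detected on all 3 arrays. Dnmt3b (-0.78 ± 0.11), Slc29a2 (-1.11 ± 0.12) and Tbx3 (-1.19 ± 0.07) were still lower than mock. Dnmt1 (-0.14 ± 0.13) and Uhrf1 (0.05 ± 0.13) did not pass. With the main settings, the medians of all other lists lay within their random ranges in this comparison.

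**Figure D3:**
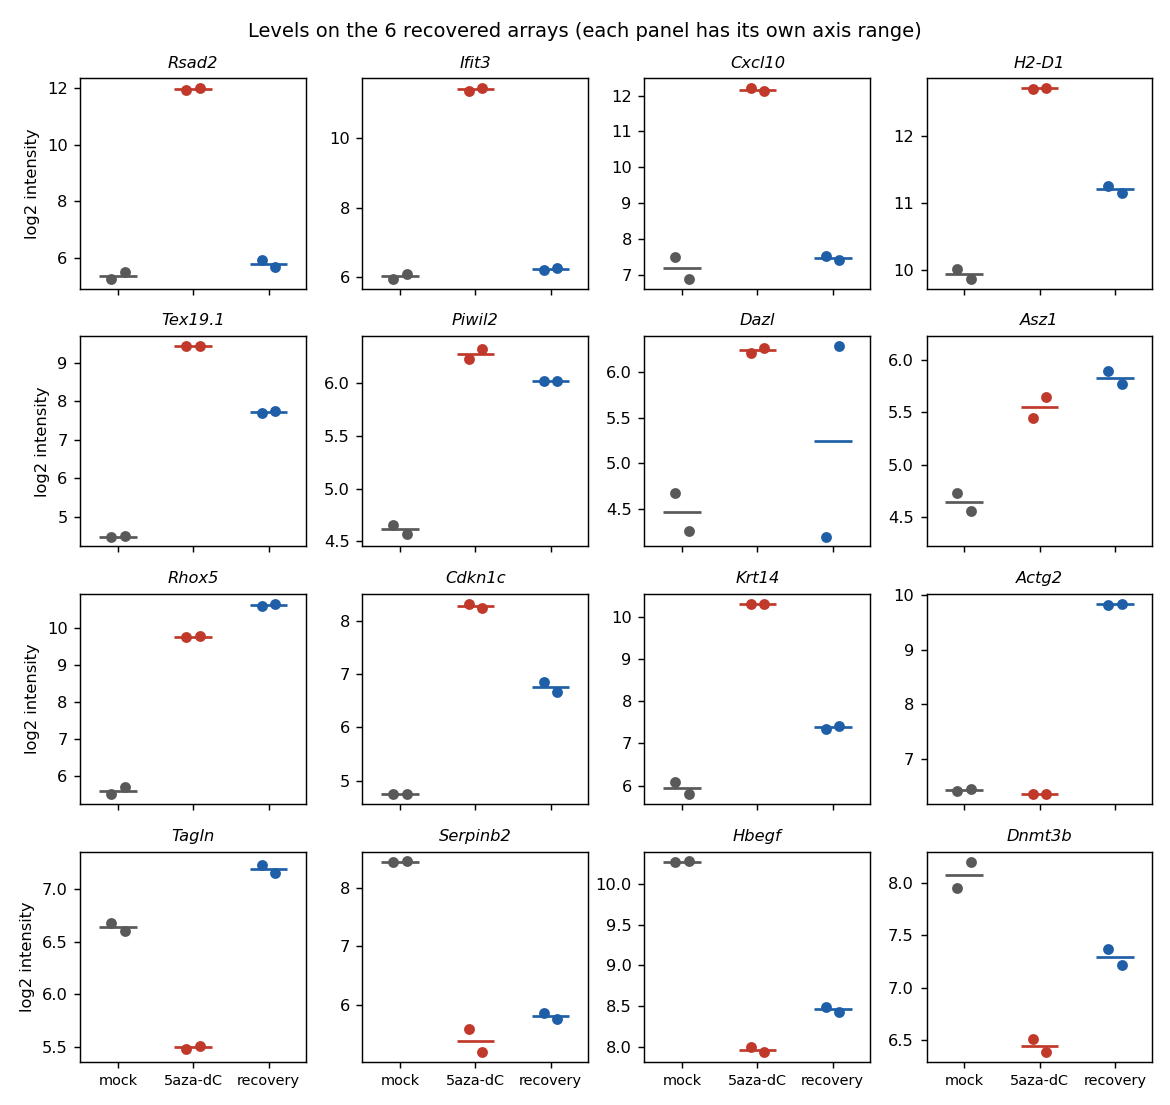
Log2 intensity of 16 genes on the 2 recovered arrays of each group (mock, 5aza-dC and recovery), 1 point per array and a bar at the mean, each panel with its own vertical axis range. Rsad2 is higher in 5aza-dC than in mock by 6.60 and in recovery by 0.43, while Rhox5 is higher by 4.19 and 5.06.

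The comparison of recovery with 5aza-dC asks what moved back after withdrawal. Interferon-induced genes fell most: Usp18 (-6.38 ± 0.15), Rsad2 (-6.18 ± 0.11), Oas1g (-5.26 ± 0.07), Ifit3 (-5.19 ± 0.08), Irgm2 (-4.92 ± 0.08) and Mx2, which was at least 31.5-fold lower. The largest rises were those of Actg2 (3.47 ± 0.07), Srpx2 (2.35 ± 0.09), the cadherin Cdh13 (1.79 ± 0.08), Mb21d2 (1.78 ± 0.10), Tagln (1.69 ± 0.08) and Sema7a (1.62 ± 0.09). In the interferon-stimulated list 41 genes fell and none rose, or 42 fell adjusted over the list alone, with a median of -2.81. All 17 class I genes fell, 17 also adjusted over the list alone (median -1.59), among them the immunoproteasome subunits Psmb8 (-3.33 ± 0.10) and Psmb9 (-2.52 ± 0.16). In the NF-kB responsive list 12 genes fell and 1 rose, or 13 and 1 adjusted over the list alone (median -0.88), with Ccl2 at -2.73 ± 0.10. Epithelial genes fell in 10 cases and rose in none, or fell in 11 adjusted over the list alone (median -1.52, or -0.15 without a detection filter), with Krt8 at -2.93 ± 0.10 and Krt14 at -2.92 ± 0.11. Germ cell genes of transposon control fell in 6 cases and rose in 1, or in 6 and 2 adjusted over the list alone (median -0.44, random range -0.30 to 0.25). That median was within its range with the series matrix values (-0.42), with a detection p-value below 0.05 (-0.12) and without a detection filter (-0.04), and it was -0.24 with undetected genes at their bound. Tex19.1 fell by 1.71 ± 0.07 and Tdrd7 by 1.19 ± 0.09, and Piwil4 was at least 2.33-fold lower. Meiosis genes fell in 5 cases and rose in none, or fell in 6 adjusted over the list alone (median -0.53, random range -0.43 to 0.25), with Taf7l at least 4.06-fold lower and Mnd1 at -1.31 ± 0.11. The meiosis median was within its range with an offset of 50 (-0.23) and over genes detected in all 3 groups (-0.06). Contractile genes rose in 12 cases and fell in 1, also adjusted over the list alone (median 0.57, random range -0.15 to 0.20), with Myl9 at 1.66 ± 0.08 and Acta2 at 1.31 ± 0.07. Matrix genes rose in 14 cases and fell in 3, also adjusted over the list alone (median 0.30, random range -0.11 to 0.16), with the collagens Col6a2 at 1.52 ± 0.12 and Col1a1 at 1.09 ± 0.10 and the proteoglycan Ogn at 1.49 ± 0.08. The matrix median was 0.11 with scaling to the median of all probes, still outside its range under that scaling. Genes switched on by p53 fell in 14 cases and rose in 3, also adjusted over the list alone (median -0.19, random range -0.14 to 0.19), with Cdkn1a, an inhibitor of cyclin-dependent kinases, at -1.14 ± 0.08. The medians of the blood cell list (-0.84, random range -0.55 to 0.37) and the oxidative stress list (-0.25, random range -0.18 to 0.23) were also low, but lay within their ranges over genes detected in all 3 groups (-0.65 and -0.15), and the blood cell median was 0.01 without a detection filter. Cda fell by 1.66 ± 0.14, and Dnmt3b rose by 0.84 ± 0.11. The adjusted p-values of the genes named in this comparison ran from 1.78e-07 for Mx2 to 0.00138 for Dnmt3b (limma with Benjamini-Hochberg adjustment). In all, 80 genes were called higher and 391 lower (17.0% higher), all of them passing limma, with 2 and 92 differing at least 4-fold, and 1952 rose and 1888 fell by limma alone. Scaling to the median of all probes gave 33 called higher and 516 lower (6.0% higher), and 28 that rose and 483 that fell by limma.

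How far the response lasted was read from the genes called in 5aza-dC. Of the 588 called higher, 87 were still at least 2-fold above mock in recovery, or 14.8% (exact 95% interval over genes 12% to 17.9%, counting error only), and the median share of the log2 rise that was left was 29.0%. By limma, 517 of the 588 (87.9%) fell between 5aza-dC and recovery, and 349 (59.4%) still differed from mock. Of the 249 called lower, 173 (69.5%) rose between 5aza-dC and recovery and 221 (88.8%) still differed from mock; the directions were not compared with each other, as the sizes of their changes differ. Of the 152 genes called higher in recovery, 86 had been called higher in 5aza-dC, against 10 if both calls were independent, and 66 were called higher in recovery alone. Among the 139 called lower in recovery, 70 had been called lower in 5aza-dC, against 3.9. Both differences share the mock arrays, which alone makes them alike. Across the 8982 genes, which are not independent replicates, the differences 5aza-dC minus mock and recovery minus mock correlated with r = 0.59. On the recovered arrays r was 0.58, and 100 simulations with no changed gene but shared mock arrays gave 0.50, with a covariance of 0.0058 against 0.167 in the data. With a different mock array for each difference r was 0.48 and 0.56. The simulations hold only the spread between the arrays of a group, so they leave out any state of the mock culture that both its arrays share. Separate mock arrays do not remove such a state either, and its part in the covariance of 0.167 is not known. None of the 37 interferon-stimulated genes called higher in 5aza-dC was still 2-fold above mock, against 2 of 14 class I genes, 2 of 8 epithelial genes, 3 of 5 germ cell genes of transposon control, 2 of 3 X-linked germ cell genes and 3 of 5 imprinted genes. Genes picked on their brightest probe and measured on their second brightest probe were still 2-fold above mock in 7.9% of cases. This covers only the 190 such genes with 2 or more detected probes, of which 49.5% were 2-fold higher in 5aza-dC on the second probe. The value is therefore not directly comparable with 14.8%, and both probes were read on the same mock arrays.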

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

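The choices of background correction, scaling, detection filter, probe and threshold were set before the data were examined, while the recovered arrays, the scaling to probes detected on all 3 arrays, the leaving out of single arrays and the separate mock arrays were chosen after the data had been seen. No paired analysis was possible because neither the labels nor the recovered arrays carry replicate numbers. Counts are given in the order higher and lower in 5aza-dC than in mock, higher and lower in recovery than in mock, and higher and lower in recovery than in 5aza-dC, against 588, 249, 152, 139, 80 and 391, and the share is that of genes still 2-fold above mock, against 14.8%. The cause of each shift was not tested. Differences shrink toward 0 near background, so an offset of 50 gave 313, 133, 64, 58, 36 and 208 and a share of 11.5%, with the meiosis median at -0.23 for recovery minus 5aza-dC and, for 5aza-dC minus mock, p53 targets at 0.17 and neural genes at 0.26. Without background correction the counts were 282, 118, 56, 44, 30 and 189 and the share 10.6%, with X-linked germ cell genes at 0.21 for recovery minus mock, and p53 targets at 0.17 and neural genes at 0.29 for 5aza-dC minus mock. Scaling by the median of all probes gave 420 lower in 5aza-dC, 73 higher and 467 lower in recovery than in mock, 33 higher in recovery than in 5aza-dC, and a share of 9.0%. Under it, for recovery minus mock, X-linked germ cell genes were at 0.19, oxidative stress genes at -0.53, interferon-stimulated genes turned to -0.05, DNA replication to -0.22 and matrix genes to -0.16, and for 5aza-dC minus mock DNA replication turned to -0.04, the DNA methylation machinery was at 0.13 and neural genes at 0.53. The median of all genes was then -0.28 for recovery minus mock, and the interferon-stimulated and matrix medians lay outside their ranges. The limma counts were then 570, 397, 67, 283, 28 and 483, against 2708, 2434, 1994, 1662, 1952 and 1888. Cyclic loess gave 53 higher in recovery than in 5aza-dC, interferon-stimulated genes at 0.16 for recovery minus mock and the DNA methylation machinery at 0.30. Scaling by the median of probes detected on all 3 arrays gave, for recovery minus mock, X-linked germ cell genes at 0.53, interferon-stimulated genes at 0.29, matrix genes at 0.18 and oxidative stress genes at -0.19. It also gave the DNA methylation machinery at 0.33 and neural genes at 0.72 for 5aza-dC minus mock, and 1156 genes higher in recovery than in 5aza-dC by limma. The series matrix values gave 263 lower in recovery than in mock and a share of 19.2%. With them the germ cell genes of transposon control were at -0.42 and oocyte genes at -0.58 for recovery minus 5aza-dC, and adipocyte genes at 0.19 for recovery minus mock. For 5aza-dC minus mock the oocyte genes were at 0.58, imprinted genes at 0.30, DNA replication at 0.15, the DNA methylation machinery at 0.40 and neural genes at 0.14. With a detection p-value below 0.05 the germ cell genes of transposon control were at 0.11 for recovery minus mock and -0.12 for recovery minus 5aza-dC, and in the latter imprinted genes were at -0.24 and endothelial genes at -0.31. Without a detection filter, which adds genes at background, the germ cell genes of transposon control were at 0.06, 0.04 and -0.04 in the 3 comparisons. For 5aza-dC minus mock X-linked germ cell genes were then at 0.04, imprinted genes at 0.01 and neural genes at 0.05. For recovery minus mock skeletal muscle genes were at 0.08, adipocyte genes turned to -0.04 and NF-kB responsive cytokines were at -0.08, and for recovery minus 5aza-dC blood cell genes turned to 0.01 and neural genes were at -0.08. Genes detected on all 3 arrays, which left the oocyte list with no genes and so no value, gave 370 higher in 5aza-dC than in mock and 217 lower in recovery than in 5aza-dC. Their medians for 5aza-dC minus mock were 0.39 for germ cell genes of transposon control, 0.34 for meiosis, 0.77 for adipocyte genes and -0.15 for neural genes, which reversed. For recovery minus mock they were 0.13 for germ cell genes of transposon control, 2.27 for X-linked germ cell genes, 0.33 for adipocyte genes and 0.62 for epithelial genes, and for recovery minus 5aza-dC -0.06 for meiosis, -0.65 for blood cell genes and -0.15 for oxidative stress genes. The X-linked value rests on few genes, Rhox5 among them. The mean of all detected probes gave contractile genes at -0.18 for recovery minus mock, and adipocyte genes at 0.45 and blood cell genes at 0.74 for 5aza-dC minus mock. Each probe on its own gave 503 lower in 5aza-dC than in mock, 229 higher and 286 lower in recovery than in mock, and 146 higher in recovery than in 5aza-dC. At least 1.5-fold gave 1365, 1009, 664, 616, 502 and 879 and a share of 32.3%, and at least 3-fold 232, 39, 33, 18, 9 and 161 and a share of 10.8%. Genes picked on the brightest probe and measured on the second gave a share of 7.9%, over only 190 genes with 2 or more detected probes. On the recovered arrays imprinted genes were at -0.28 for recovery minus 5aza-dC, DNA replication at 0.15 for recovery minus mock and the DNA methylation machinery at 0.27 for 5aza-dC minus mock. With 5aza-dC set against mock array 1 and recovery against mock array 2, r was 0.48 against 0.59. Leaving out 1 recovered array, which assumes that the remaining array of its group varies like the other groups, gave by limma 1180 to 2101 genes higher and 945 to 1739 lower in recovery than in mock. Without recovery array 1 or 2 these were 1189 and 1180 higher and 945 and 1031 lower. For recovery and 5aza-dC it gave 1054 to 2334 higher and 1209 to 2178 lower, with 1054 and 1095 higher without 5aza-dC array 1 or 2, 1170 and 1184 higher without a recovery array, and 1209 lower without 5aza-dC array 1. Undetected genes at their bound gave a share of 15.2%. Of 888 list medians under alternatives, 826 stayed on their side of the limits of the random lists, 26 moved inside, 29 moved outside and 7 changed direction with at least 1 value outside. The size of a median was not part of that count: epithelial genes for 5aza-dC minus mock ran down to 0.13 from 1.58, and mitotic genes for recovery minus mock to 0.02 from 0.41, both still outside their ranges. Of 1976 values of named genes under 8 alternatives, 895 moved by more than 1 SE and 150 values of called genes were under 2-fold. Of 189 called values, 65 were under 2-fold in some alternative and 124 were at least 2-fold in all, and none changed direction.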

Other observations

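Genes of growth factor signalling and ribosome assembly factors were lower in 5aza-dC than in mock, and both lists were written after the named genes had been seen. Of 35 detected growth factor responsive genes (43 measured), 22 fell and 6 rose in 5aza-dC, or 23 and 7 adjusted over the list alone, with a median of -0.51 against a random range of -0.20 to 0.21. In recovery 20 fell and 3 rose against mock, or 22 and 3 adjusted over the list alone, with a median of -0.52 against a random range of -0.12 to 0.18. Between recovery and 5aza-dC the median was 0.06, with 12 that rose and 9 that fell, or 13 and 9 adjusted over the list alone. The following genes were chosen after their values had been seen: Phlda1 differed from mock by -1.86 ± 0.08 in 5aza-dC and -1.12 ± 0.08 in recovery, the ERK phosphatase Dusp6 by -1.26 ± 0.08 and -0.74 ± 0.08, and the transcription factor Myc by -1.22 ± 0.09 and -0.95 ± 0.09 (limma, n = 2 arrays per group). Egr1 fell by 0.85 ± 0.11 in 5aza-dC, while its value of -0.32 ± 0.11 in recovery did not pass. Of 27 detected ribosome assembly factors (33 measured), 25 fell and none rose in 5aza-dC, also adjusted over the list alone, with a median of -0.77. In recovery 19 fell against mock, or 20 adjusted over the list alone (median -0.41), and 16 rose against 5aza-dC, or 17 adjusted over the list alone (median 0.35). Among them the polymerase I subunit Polr1b differed by -1.41 ± 0.11 in 5aza-dC and -0.49 ± 0.11 in recovery, nucleolin (Ncl) by -0.98 ± 0.07 and -0.29 ± 0.07, and Nop56 by -0.79 ± 0.08 and -0.42 ± 0.08.

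For the interferon-stimulated genes, the tests of scaling, of 1 array alone and of blood cells were chosen only after the result was seen, and the test of interferon genes was set before. Between-array scaling or background correction left the list median at 1.97 or more, 1 array of a pair alone gave 2.74 or more, and of 25 measured blood and immune cell genes only 1 (Laptm5) was called higher, so none of these accounts for the rise. Of 20 interferon genes measured, 4 were detected in 5aza-dC and 2 each in mock and recovery, and Ifnb1 was detected only in 5aza-dC (at least 1.74-fold), as was Ifnz (at least 1.02-fold). Ifna6 (log2 level 5.63 in mock and 5.27 in 5aza-dC) and Ifnab (6.57 and 6.46) were detected in all 3 groups and were not higher in 5aza-dC, all 4 being named after their values had been seen. The values set beforehand for and against interferon genes switched on in the treated cells were thus both met, and this explanation stays open.

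For the lasting rise of germ cell and imprinted genes, the draws matched on detection in mock alone were chosen only after the result was seen, and the other tests were set before. Of 14 such genes called higher in 5aza-dC, 8 (57.1%) were still 2-fold above mock in recovery, against 79 of 574 other genes called higher, which include 37 interferon-stimulated genes of which none was. In draws of other called genes, matched on detection in mock and taken from the 20 nearest in rise, 0.04% of 10000 reached 8, with a mean of 2.4. The level in mock itself was not matched. Interferon-induced genes made up most of the largest rises, so they could dominate the matches of the germ cell and imprinted genes that rose most. Whether a low level in mock and the size of the rise account for the pattern thus remains undecided. A fixed detection floor in mock was not decided by its own test, as 14.9% of the genes not detected in mock were still 2-fold higher against 14.7% of those detected and the value set beforehand against it was a share at or below the latter. Detection in mock alone does not account for the pattern, since 0.01% of 10000 draws matched on it reached 8 (mean 1.9), and 5 of 9 undetected and 3 of 5 detected genes were still higher. Dazl, 1 of the 8, was high on only 1 recovery array and did not pass limma.

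For the growth factor responsive genes, the tests of 1 array alone and of the mock culture were chosen only after the result was seen, and those of scaling and of the picked genes were set before. 1 array of a pair alone gave medians of -0.45 or lower, between-array scaling or background correction -0.30 or lower, and the 29 members not among the named genes -0.38 or lower. The fall was thus not confined to the named members. The list itself was written after falls on these same arrays had been seen, so this test cannot exclude that its genes were picked because they were low. The state of the mock culture at harvest remains open: the median of 0.06 between recovery and 5aza-dC is in line with it and also with a lasting effect of the drug. More than 1 mock culture, harvested at matched density, would separate both.

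Neighbours were genes next to each other among the detected genes, and genes whose symbols begin with the same letters were taken as 1 family, which is only approximate. Neighbouring genes were tested as set before the result was seen: genes called higher in 5aza-dC formed 70 neighbouring pairs against 38.3 in shuffled orders (permutation p = 0.0002), but without pairs of 1 gene family 47 against 37.0 (permutation p = 0.049, upper limit of the shuffles 48). Genes called higher in recovery formed 7 such pairs against 2.5 (permutation p = 0.012), and 5 against 2.4 without pairs of 1 family (permutation p = 0.095, upper limit of the shuffles 6). Among 2105 detected probes without a gene name, 101 were called higher and 95 lower in 5aza-dC than in mock, 20 of the higher ones were still 2-fold above mock in recovery, and 28 were called higher in recovery.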
